A study of Drosophila melanogaster with 2 samples.

How the data were processed

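Whole embryos of a Drosophila line with Hand fused to green fluorescent protein were assayed by chromatin immunoprecipitation and sequencing in 2 biological replicates. Chromatin was sonicated to 200 to 800 bp, per the labels. The deposited files were peak lists on the dm6 and dm3 builds. Per the file listing deposited with the samples, each replicate's list and a pooled list were called against a control alignment that the replicates shared, and the thresholded list came from a reproducibility (IDR) comparison of those lists. The aligner, the peak caller, its settings, the IDR threshold and the read depth are not given in the sources used here. Control alignments and reads were not analysed here.

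Each row of a deposited list held a peak's position, its summit, a signal value and a q-value. The deposited signal is the authors' peak caller's own value, against the control and not rescaled between lists. It was used to describe, rank and filter peaks, to compare medians of gene lists within a peak list, and to correlate the replicates across peaks. The deposited q-value is given as −log10 and was not used to rank, because the highest value was shared by 2762 of the 3310 thresholded dm6 peaks. Lists called with background held exactly 30000 peaks each, and the thresholded lists held 3310 peaks on dm6 and 3184 on dm3. All 3310 were found in the pooled dm6 list with the same position and signal, and they were its 3310 strongest peaks, so their signal is a pooled value with no error. Peak signal in the dm6 lists reached 2061 in the thresholded list, 729 in replicate 2 and 1372 in replicate 3. No peak had the same position and signal in both replicates' lists.

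Analyses used dm6 coordinates, printed from 1, with the reference genome of that build and the protein-coding genes of Ensembl release 115 on the 6 main arms. The dm3 lists served only for counts, overlap and correlation. Gene symbols in the fixed lists were all matched, 8 of them through a current name. Programs were written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

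Shared peaks were summits within 100 bp of each other, among the top 3310 peaks by signal of each replicate, and the share expected came from 100 random placements. Location classes were promoter (within 500 bp of a TSS), then exon, intron and intergenic, and were compared with 1000 random placements within the arm. A gene had a peak if a thresholded summit lay in its body or within 2 kb. The share of each of 15 gene lists was compared with 10000 random lists matched on gene length in 20 bins. Each of 20 sequence words was sought on both strands within 50 bp of the summit and in the 101-bp window centred 400 bp to the left, with an exact McNemar test. Median signal of a list's peaks was compared with other assigned peaks by 100000 draws of labels, for lists with at least 5 peaks. All tests were two-sided with Benjamini-Hochberg adjustment within each family, and 0.05 was the threshold. Their p-values cover the choice of positions, genes or peaks and not the spread between embryos, since the thresholded list pools both replicates. Intervals and p-values treat peaks and genes as independent, which neighbours are not.

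The lists, words, tests and alternatives were fixed before the data were examined. So was the rule for named genes: those nearest by TSS to the 20 strongest thresholded peaks, the 3 members with the strongest assigned peak in each list, and always Hand, da and tin. Heart regulators without a thresholded peak, Ufd4 beside the Hand peak, and members named in the closing section, were chosen after their values were seen. Alternatives were other summit distances and overlaps, list lengths, the dm3 build, promoter windows of 200 and 1000 bp, gene bodies alone or with 5 kb, the gene nearest by TSS, random lists matched on the distance between neighbouring genes, Fisher's exact test, the stronger 1655 peaks, motif windows of 25 and 100 bp, the right flank, and each replicate's own top 3310 peaks in place of the thresholded list.

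The procedures were tested on simulated data. With randomly placed peaks, 2.5% of 200 random lists of 25 genes had p under 0.05. Of these lists, 99.0% were found once 8 more of their genes were given a peak. Of 20 sets of randomly placed peaks, 1 passed the promoter test and 1 the motif test by chance. All 20 were found after 10% of the summits had been moved to a TSS, and likewise after 3% of the peaks had been given the word. Randomly placed peaks lack the promoter share and base composition of the real summits, so these rates need not hold for the real peaks. Of 100 random lists of 20 peaks, 8% passed the strength test, and 100% were found once their signal was doubled.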

Results

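The series assayed binding of the transcription factor Hand along the genome of whole Drosophila melanogaster embryos. Hand is a basic helix-loop-helix factor of the dorsal vessel (the fly heart), the pericardial cells beside it, the lymph gland and the visceral muscle. The embryos were of mixed sex, 6 to 24 hours old, and came from a transgenic line carrying Hand fused to green fluorescent protein. Chromatin was immunoprecipitated with an antibody against that protein and sequenced. There was 1 group with 2 biological replicates, labelled replicate 2 and replicate 3, and no untreated or control library was among the samples, so no contrast between groups was possible. Each replicate had a list of 30000 ranked peaks, most of them weak, and a shared list held 3310 peaks on the dm6 build. The authors' reproducibility threshold kept these, and they were the strongest peaks of the pooled list. Not all of them recurred in each replicate. A summit lay within 100 bp for 93.9% in replicate 2's full list and for 97.0% in replicate 3's. The read depth behind the lists is unknown.

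Peaks of Hand-GFP lay mostly at promoters and in introns. Of the 3310 thresholded summits, 1643 (49.6%) fell within 500 bp of a protein-coding transcription start site (TSS), against 11.5% of random positions, a ratio of 4.32. Another 1167 (35.3%) were in introns, 452 (13.7%) were intergenic and only 48 (1.45%) were in exons, where random placement put 39.3%, 29.9% and 19.3%. The median summit lay 512 bp from the nearest TSS, with quartiles at 134 bp and 2720 bp. Equally long top lists of the single replicates averaged 49.8% ± 0.641 promoter summits (SD, n = 2), 1.66% ± 0.513 in exons, 35.1% ± 0.449 in introns and 13.5% ± 0.320 between genes, so each departure from random was larger than the spread between replicates. All 4 classes had an adjusted p of 0.002, the smallest that 1000 random placements can give (permutation test, two-sided, Benjamini-Hochberg). With a 200-bp promoter window the intron share turned to above random, 43.1% against 41.1% (adjusted p = 0.018, same permutation test).

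**Figure D1:**
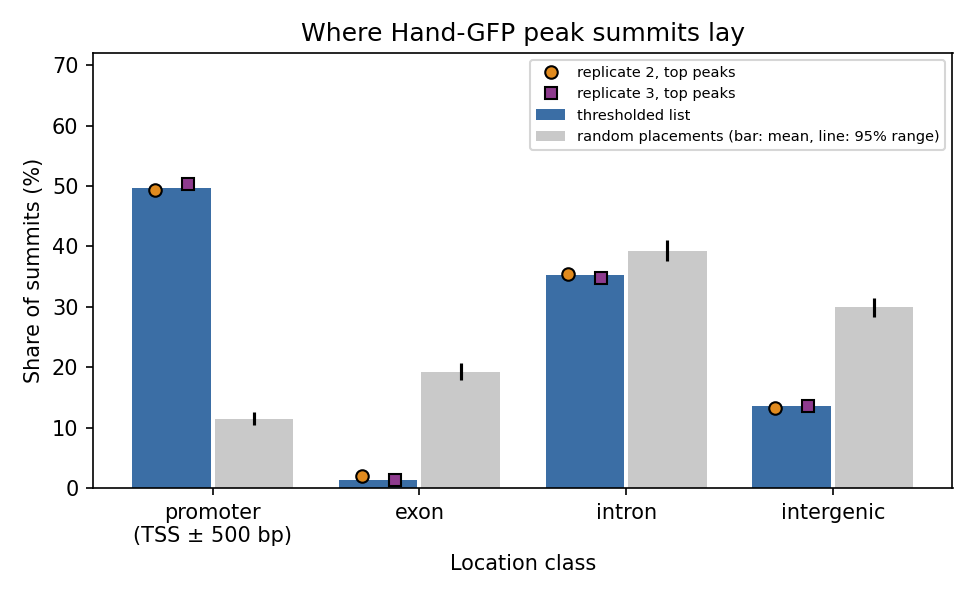
Share of peak summits (y axis, percent) in each location class (x axis) for the thresholded list (blue bars), random placements (grey bars with the 95% range as a line) and the top 3310 peaks of each replicate (points). Promoters held 49.6% of the thresholded summits and 11.5% of random positions, and both replicates sat close to the blue bars.

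The peaks covered all 6 main chromosome arms. Arm 2L held 633 peaks (26.9 per Mb), 2R 617, 3L 687, 3R 761 and X 601 (25.5 per Mb), while the small arm 4 held 11 (8.16 per Mb).

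The 20 strongest peaks were nearest to genes of varied function, and none of these nearest genes was in the heart, pericardial, visceral muscle or blood lists. The highest signal, 2061 in the thresholded list, was at 2L 480822-481341 (dm6), 1377 bp upstream of cbt, which codes for the zinc-finger factor Cabut, and inside an intron of ush, which codes for a cofactor of GATA factors in blood and heart and is in the blood list, where this peak counts for it. Its signal was 653 in replicate 2 and 1372 in replicate 3. Next came an intronic peak of CG11050 at 2L 6612398-6612912 (signal 2029) and a peak at X 2703686-2704082, 42 bp upstream of the TSS of the UDP-galactose transporter gene Ugalt (signal 1857). A peak 5010 bp from the TSS of CG4004 had signal 1486, and one 143 bp upstream of Gapdh2, a glycolytic enzyme gene, had 1382. The peak at X 2137686-2138120 in the 5' UTR of ph-p had signal 995, and that at 2R 12985022-12985393, 4223 bp upstream of Psc, had 953. Both genes code for Polycomb group proteins, and Trl, with an intronic peak of signal 1314, codes for the GAGA factor. The other peaks among the 20 strongest were nearest to px (1293), CG14100 (1271), CG32772 (1210), Tlk (1150), Lk6 (1125), amon (1117), CG9663 (1098), HmgZ (1044), larp (963), chif (958), CG31145 (933) and CenG1A (929). All 20 were present in the lists of both replicates.

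The sequence under the strongest peaks was rich in A and T. The window of 50 bp on each side of the cbt summit (2L 481015-481115) read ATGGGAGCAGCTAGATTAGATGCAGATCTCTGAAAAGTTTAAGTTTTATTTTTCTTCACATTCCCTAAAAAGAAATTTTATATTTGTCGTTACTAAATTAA, with 72.3% A or T and 0 words CANNTG, the E-box bound by this class of factor. The CG11050 summit window had 78.2% A or T and 0 E-boxes, and the Ugalt window had 66.3% and 1 E-box.

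The tagged gene had 1 assigned thresholded peak. It lay at 2L 10292234-10292669, with signal 234 and rank 629 of 3310. Its summit was 227 bp beyond the 3' end of Hand (FBgn0032209, 2L 10292679-10295385, minus strand) and 87 bp from the neighbouring gene Ufd4, which the peak overlapped by 132 bp. Replicate 3 had a peak with a summit within 100 bp, of signal 171, and replicate 2 had none there. The window of 50 bp on each side of that summit (2L 10292402-10292502) held 0 E-boxes. In the 90 kb centred on Hand, replicate 2 listed 4 peaks and replicate 3 listed 36, while other windows of that length averaged 20.2 in each list. The lists do not settle whether the library labelled replicate 2 carried the tagged construct, so its peaks and the pooled list are Hand-GFP peaks by label only. Without that library, the top 3310 peaks of replicate 3 had 50.3% promoter summits and reached 10 of 25 heart genes. These values do not settle the matter, because 60.8% of replicate 2's top 3310 peaks had a summit within 100 bp among them. The gene of the partner protein Daughterless, da, had no thresholded peak in its body or within 2 kb, while the weaker peaks of both replicates' full lists and the pooled list included some inside it, with pooled signal up to 75.1. Its nearest thresholded summit was 6009 bp away, at 2L 10381878-10382313, with signal 308, and 71.2 in replicate 2 and 223 in replicate 3. The heart gene tinman, tin, had a peak 186 bp upstream of its TSS at 3R 21378573-21379008, with signal 123, rank 2001, and 34.2 and 92.8 in replicates 2 and 3.

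**Figure D2:**
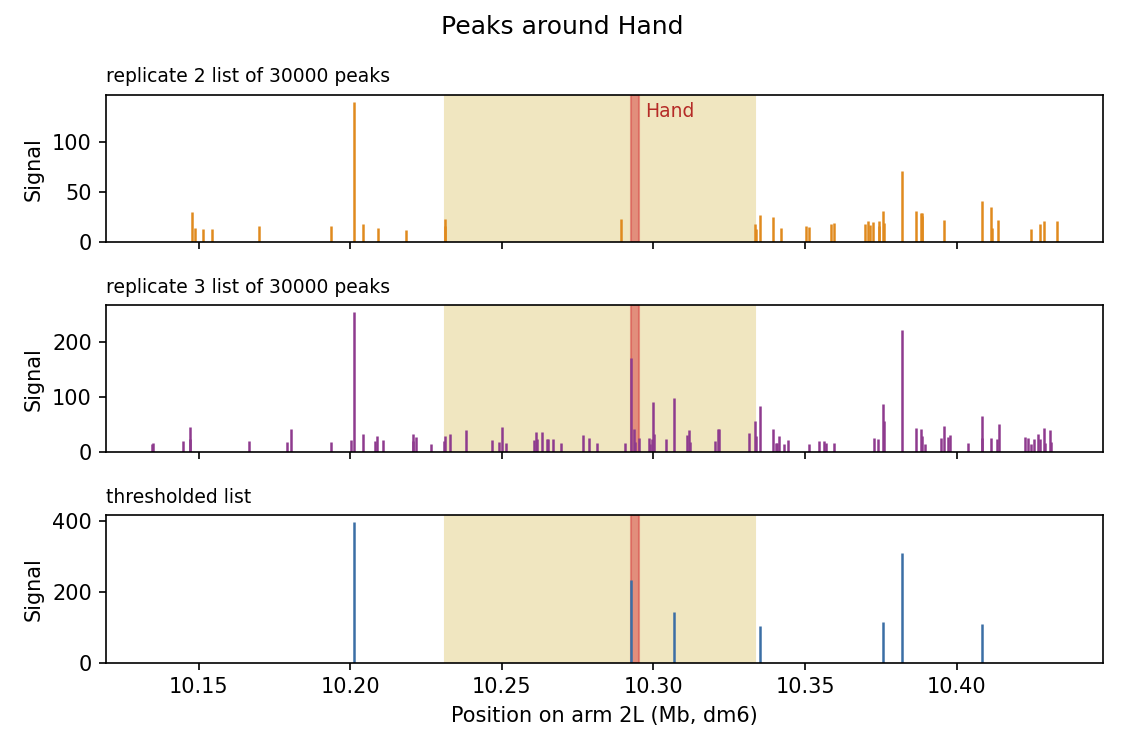
Peaks around Hand on arm 2L (x axis, Mb, dm6) in the lists of replicate 2, replicate 3 and the thresholded list (y axes, peak signal on each list's own scale, from 0). Lines mark summits and red marks Hand. The shaded 102 kb was chosen as the longest stretch around Hand with at most 1 replicate 2 peak, and it holds 37 replicate 3 peaks.

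The question the design poses next is whether genes of the organs that express Hand had peaks more often than other genes of like length. They did not pass that test in either direction. Of 13945 protein-coding genes, 3579 (25.7%) had a thresholded summit in the gene body or within 2 kb. Of the 25 heart genes, 10 (40.0%) had one, against a mean of 41.0% in random lists matched on length (95% range 24% to 60%). Mef2, the myogenic factor, had 7 peaks, the strongest 1051 bp from a TSS at 2R 9959721-9960086 with signal 915, rank 21. Sur had 1 peak of signal 396, whose summit was also 35 bp from the TSS of RpL7. The cardiac regulators pnr, mid, H15, svp, Doc1, Doc2 and Doc3 had no thresholded peak. Of the 13 pericardial genes 5 had a peak (38.5% against 39.3%), led by the fusion gene kirre with 10 peaks (strongest signal 278) and the zinc-finger gene zfh1 with 1 (250). Of the 21 visceral muscle genes 8 did (38.1% against 41.6%), including kirre, Hand and the forkhead gene bin, with 2 peaks and signal 218. Of the 25 blood genes 9 did (36.0% against 39.1%), led by ush with 12 peaks (strongest signal 2061, the peak named above), zfh1, and Stat92E with 2 peaks (signal 215). Like that of Hand, the strongest peaks of bin and Stat92E had no replicate 2 summit within 100 bp. The adjusted p was 1 for each of these 4 lists (permutation test against 10000 random lists, two-sided, Benjamini-Hochberg over 15 lists). Against random lists matched on the distance between neighbouring genes the direction turned for all 4, with expected means of 27.9% for heart, 29.1% for pericardial, 29.8% for visceral muscle and 27.1% for blood, and none passed (adjusted p from 0.668 to 0.844, permutation test). Random ranges this wide leave moderate differences undetectable with lists of this size.

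Genes of the cytosolic ribosome had peaks far more often than length-matched random lists. Of 92 genes, 67 (72.8%) had a peak, against a mean of 18.4% in random lists (95% range 10.9% to 26.1%), with an adjusted p of 0.003 in the same permutation test and the smallest raw p it can give, 0.0002. The top 3310 peaks of replicate 2 reached 66 of the genes and those of replicate 3 reached 69. The strongest were RpS4 with signal 433, its summit 14 bp from the TSS at 3L 13041678-13041926, RpS27 with 424 at 3R 25247359-25247634, and RpL7 with 396 at 2L 10200941-10201179, each with its summit within 50 bp of a TSS. Ribosomal peaks were also stronger than others, with a median signal of 172 over 86 peaks against 136 (adjusted p = 0.0272, permutation test of labels, two-sided). That difference did not pass in replicate 2 alone, 61.5 against 51.99 (adjusted p = 0.149, same permutation test). The draws of labels were not matched on peak location, and promoters held 52.6% of the stronger 1655 thresholded summits against 49.6% of all 3310.

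**Figure D3:**
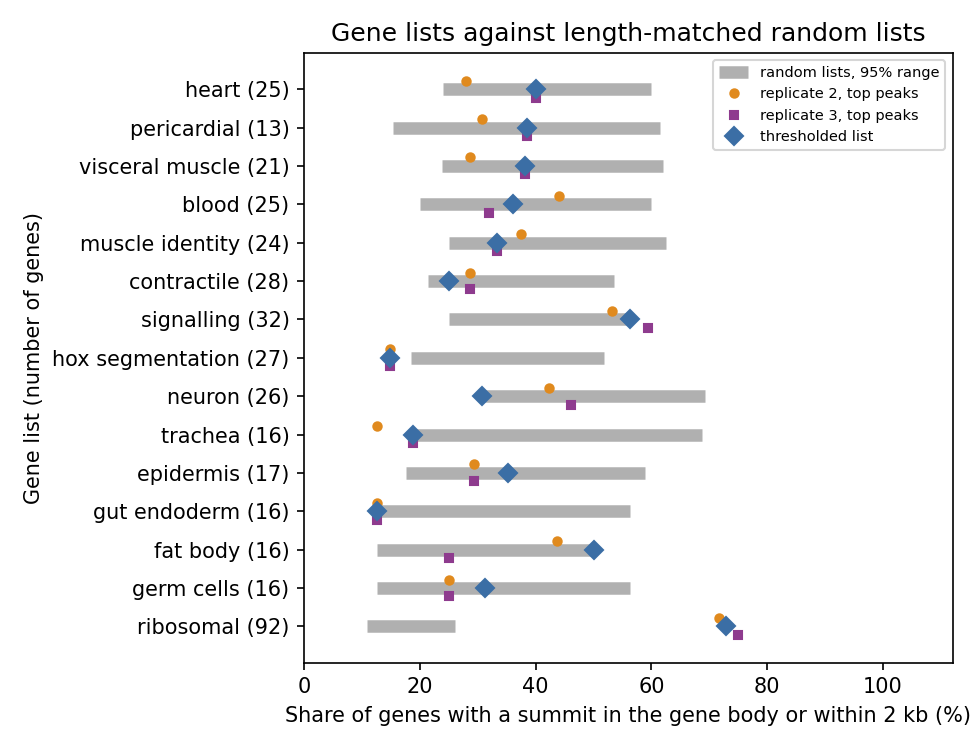
Share of genes with a peak (x axis, percent) for each fixed gene list (y axis, number of genes in brackets) in the thresholded list (diamonds) and the top peaks of each replicate (circles, squares), with the 95% range of length-matched random lists in grey. The ribosomal list stands at 72.8%, far right of its grey bar, while the heart list at 40.0% lies inside its own.

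None of the other 10 lists passed the test. Signalling genes had peaks at 18 of 32 (56.2% against 41.0%, adjusted p = 0.233, permutation test), among them the bone morphogenetic protein gene gbb (signal 657), its pathway inhibitor Dad (379) and Med (339). With random lists matched on the distance between neighbouring genes, that share was compared with 27.6% and passed (adjusted p = 0.009, permutation test). Hox and segmentation genes had peaks at 4 of 27 (14.8% against 36.0%, raw p = 0.0222, adjusted p = 0.166, permutation test), of which hb had signal 344, Abd-B 199 and Antp 142. Muscle identity genes reached 8 of 24, led by how (241), org-1 (195) and stumps (191). Contractile genes reached 7 of 28, led by Msp300 (519), tmod (288) and Zasp52 (228). Markers of other embryonic cells also missed the threshold. Neuronal genes had peaks at 8 of 26 (30.8% against 49.0%), or 46.2% without replicate 2, including elav (824), the glial gene moody (585) and ChAT (418). Tracheal genes had peaks at 3 of 16, namely trh (409), bnl (96.0) and rib (94.98), and epidermal genes at 6 of 17, led by mwh (206), sn (156) and grh (140). Gut endoderm genes reached 2 of 16, fkh (396) and Hnf4 (194). Fat body genes reached 8 of 16 (against a mean of 30.2%), but 4 without replicate 2 (25% against 31.6%), led by Mtp, Adh (both 216) and Apoltp (209), and germ cell genes 5 of 16, led by bgcn (191), gcl (113) and piwi (108). The strongest peaks of bnl, mwh and gcl had no replicate 2 summit within 100 bp, and that of Antp had none in replicate 3. The Hox and segmentation share lay below its random range, the neuronal, tracheal and gut endoderm shares at the lower end of theirs, and the signalling and fat body shares at the upper end. No list other than the ribosomal one differed in peak strength, with adjusted p from 0.268 to 0.900 in 13 permutation tests, and the tracheal list had too few peaks for it.

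E-boxes, the words that Hand and its partners bind, were not more frequent under the summits. CATCTG, the word tested for Hand with Daughterless, occurred within 50 bp of 88 summits (2.66%) against 3.23% of windows 400 bp to the left (adjusted p = 0.395, exact McNemar test). It passed as lower with 100 bp on each side, 5.68% against 7.25% (adjusted p = 0.0317, same exact test), and among the 1655 strongest peaks, 1.99% against 3.38% (adjusted p = 0.0426, same exact test). The general E-box CANNTG occurred at 34.7% of summits against 39.2%, a ratio of 0.885, and was the only one of 20 words that passed as lower (adjusted p = 6.28e-04, exact McNemar test). The direction was the same in replicate 2 (36.0% against 39.8%) and replicate 3 (35.6% against 40.2%). With 25 bp on each side the difference missed the threshold, 18.7% against 21.0% (adjusted p = 0.0615, same exact test).

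Words of 5 other factor classes were more frequent at summits. The forkhead word RTAAAYA was at 23.8% of summits against 14.6% of flanks (ratio 1.63, adjusted p = 2.88e-20), the Mef2 word YTAWWWWTAR at 6.86% against 2.99% (ratio 2.29, adjusted p = 2.51e-12) and the GATA word WGATAR at 22.0% against 16.8% (ratio 1.31, adjusted p = 5.76e-07, exact McNemar tests). The ETS word ACCGGAAR was at 34 summits (1.03% against 0.302%, adjusted p = 0.00155) and the DREF word TATCGATA at 33 (0.997% against 0.453%, adjusted p = 0.0443, exact McNemar tests). All 5 were higher in both replicates. With 25 bp on each side the ETS and DREF words missed the threshold, at 0.544% against 0.151% and 0.574% against 0.181%. Beside these values stands the base composition, which was 64.4% A or T at summits and 56.6% in the same flanks, and 70.0% at the 331 strongest summits. The words for Tinman, T-box factors, Twist, the GAGA factor, Zelda, Su(H), STAT, AP-1, Grainyhead and M1BP did not pass. The tests were exact McNemar tests over peaks, two-sided with Benjamini-Hochberg adjustment over 20 words, and their p-values cover the choice of peaks, not the spread between embryos.

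**Figure D4:**
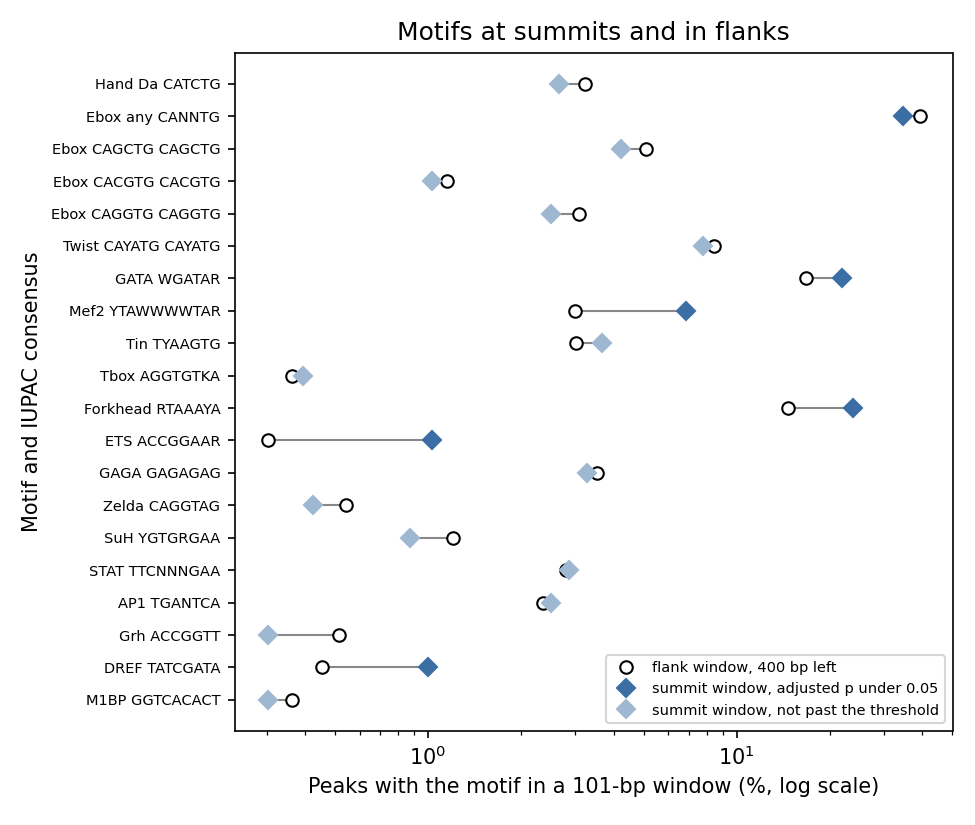
Share of the 3310 peaks with each word (y axis, with its consensus) within 50 bp of the window's centre, in percent on a log scale (x axis), at the summit (diamonds, dark where the adjusted p passed) and 400 bp to the left (open circles). The forkhead word stands at 23.8% against 14.6%, and the general E-box at 34.7% against 39.2%.

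The replicates shared most of their strong peaks. Of the 3310 strongest replicate 2 peaks, 2011 (60.8%, 95% Wilson interval 59.1% to 62.4%) had a summit within 100 bp among the 3310 strongest of replicate 3, against a mean of 0.482% for random placements. The thresholded list was itself selected by a comparison of these lists, so its presence in both full lists is no separate evidence of agreement. Over the 3015 thresholded peaks with a summit within 100 bp in both full lists, the signals correlated with Spearman's rho 0.654 and Pearson's r 0.758 on the log2 scale, across peaks, which are not independent replicates. Both lists were called against the same control, so part of the excess over random may come from that shared control. An exact sign-flip test over 2 replicates cannot give a p below 0.5, so none was run across replicates.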

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

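The alternatives here were fixed in advance, except the comparison with the pooled list's other peaks, which was chosen after seeing the data. Location classes kept their direction and their side of the threshold in 23 of 24 alternatives. The exception was the intron share with a 200-bp promoter window, 43.1%, where introns took over part of the promoter class by construction. Against the pooled list's other 26690 peaks, promoters still held more of the thresholded summits (49.6% against 26.0%). The 2 rank correlations kept within 0.05 of the main value. The number of peaks was 1655 in the stronger part by construction. Overlap between replicates was 69.8% within 250 bp, 70.8% for 1 shared bp, 58.8% for 50% of each other, 69.2% for the 1655 strongest of each and 52.5% for lists of doubled length, and stayed inside its interval on dm3.

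The ribosomal list passed under all 8 alternatives. With lists matched on the distance between neighbouring genes, and by Fisher's exact test, 2 lists passed, the second being signalling. The other 13 passed in none, but the direction of some turned without a call, and the cause was not tested. Against lists matched on neighbour distance, and by Fisher's exact test, the shares stood above expectation for heart (40.0%), pericardial (38.5%), visceral muscle (38.1%), blood (36.0%), muscle identity (33.3%), neuronal (30.8%), epidermal (35.3%) and germ cell genes (31.2%). The means expected with neighbour distance were 27.9%, 29.1%, 29.8%, 27.1%, 27.7%, 28.6%, 27.7% and 27.5% in that order. By nearest TSS the turned shares were heart 32.0%, pericardial 38.5% and epidermis 29.4%. With 5 kb they were epidermis 47.1% and germ cells 56.2%, and among the stronger peaks visceral muscle 33.3%. Leaving out each replicate gave blood 32.0% to 44.0% and fat body 25% to 43.8%.

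Median signal by nearest TSS was 119 for blood, against 136 for other assigned peaks. Leaving out each replicate gave medians, on each list's own scale, of 44.1 to 91.1 for heart, 47.1 to 128 for visceral muscle, 54.0 to 88.7 for blood, 51.3 to 91.3 for muscle identity, 49.7 to 81.5 for contractile, 56.7 to 72.3 for epidermis, 49.5 to 109 for fat body and 61.5 to 114 for ribosomal genes. The lower value is replicate 2's and the higher replicate 3's. Other assigned peaks had medians of 51.99 to 52.3 and of 88.9 to 89.4. The direction turned for heart, blood and muscle identity in replicate 3, for visceral muscle, epidermis and fat body in replicate 2, and for contractile genes in both.

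CATCTG passed as lower at summits with 100 bp (5.68%) and among the stronger peaks (1.99%), and CANNTG missed with 25 bp (18.7%). The number of words higher was 3 with 25 bp, and the number lower was 0 with 25 bp, 3 with 100 bp, 2 against the right flank and 4 among the stronger peaks. Words that turned without a call were CAGCTG (9.64%), STAT (5.498%) and M1BP (0.846%) with 100 bp, CAYATG (4.14%) and STAT (1.27%) with 25 bp, Tinman against the right flank (3.66%) and M1BP among the stronger peaks (0.302%). Leaving out each replicate gave GAGA 3.11% to 4.41%, Grainyhead 0.393% to 0.483% and M1BP 0.151% to 0.544%. Of 305 counts of peaks at named genes, 235 stayed within 1.5 times. Hand and tin each had 0 assigned peaks in the top list of replicate 2. No paired analysis was possible because there was 1 group. Depth limits were not assessed, since depth is unknown.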

Other observations

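All families and tests in this part were chosen after the strongest peaks and the region around Hand had been seen, except that the tests on housekeeping families, length-matched lower-ranked peaks and reordered words other than those of CATCTG were set before their results were seen. Genes of stress and early transcriptional responses carried peaks unusually often, 10 of 12 (83.3%) against a mean of 37.1% in length-matched random lists (adjusted p = 0.0066 over 12 families, permutation test, two-sided). They were the AP-1 genes kay and Jra, the phosphatase gene puc, Atf3, Xrp1, Irbp18, Gadd45, Hr38, Thor and cbt. The list was drawn up knowing that cbt had the strongest peak, so it is not independent evidence. The top lists of replicates 2 and 3 reached 10 and 11 of the 12 genes. Mitochondrial ribosomal protein genes had peaks at 24 of 73 (32.9% against 15.9%, adjusted p = 0.004, same permutation test).

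The Cpr and chemoreceptor families had peaks less often than length-matched random lists. Cuticle protein genes of the Cpr family had peaks at 0 of 70 against 19.2%, and chemoreceptor genes of the Or, Gr and Ir families at 10 of 179 (5.59%) against 21.6%. Both had an adjusted p of 0.0012 in the permutation test, two-sided, and the replicates' top lists gave 1 and 0 of the cuticle genes and 8 and 9 of the chemoreceptor genes. Members of these families lie in clusters, so genes are not independent in this test. Polycomb and trithorax genes had peaks at 11 of 20 (55.0% against 37.6%, adjusted p = 0.273) and heat shock genes at 8 of 19 (42.1% against 22.5%, adjusted p = 0.195), which did not pass the permutation test. Translation factors (16 of 51), proteasome (9 of 32), tRNA synthetase (6 of 17), ATP synthase (4 of 15), complex I (6 of 40) and odorant-binding genes (4 of 51) did not pass either.

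Around the tagged gene itself, the longest stretch with at most 1 replicate 2 peak was 102 kb (2L 10231336 to 10333628, 35 protein-coding genes). Its ends were replicate 2 summits, so its low replicate 2 count was set by that choice. It held 37 replicate 3 peaks, while the most in any other stretch with at most 1 replicate 2 peak was 15. Chance unevenness is argued against by the other 13319 overlapping 90-kb windows, whose highest standardised difference was 3.46, against 5.06 for the window centred on Hand. Both lists held exactly 30000 peaks, so their counts cannot show whether the immunoprecipitation was generally weaker in replicate 2. Windows with a like replicate 3 count held at least 16 replicate 2 peaks where the Hand window held 4, so no such window was as low. The 100 kb on each side also had fewer, 42 against 63. That ratio of 0.667 fell just under the first bound set, 0.67. A candidate explanation, more copies of a construct with the Hand region in replicate 3 and the control than in replicate 2, cannot be told apart from a deletion, a different line or a mislabelled library, because the control was not analysed here and the replicate 3 count lay at the ordinary 88.4 percentile of other windows; no biological explanation was tested. If replicate 2 lacked the tag, its peaks, the 60.8% overlap and the pooled thresholded list would not measure Hand binding. The replicate 3 peaks within that overlap could then not be taken as specific to Hand either.

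Ribosomal protein genes exceeded random lists while the heart, pericardial, visceral muscle and blood lists did not. Binding at broadly active promoters in general cannot be told apart from a ribosomal preference, since 1 of 3 other housekeeping families (mitochondrial ribosomal) passed and the proteasome and tRNA synthetase lists are small, with random ranges up to 34.4% and 47.1%. Hand targets in few cells, with peaks too weak for the threshold, would give an excess at lower ranks. The test set beforehand found none as far as rank 10000. Pooled peaks ranked 3311 to 10000 lay at 46.8% of the 77 genes of those 4 lists. Length-matched random lists had a mean of 59.5% and a range from 49.4% (p = 0.0224, permutation test, two-sided). Lists matched on the distance between neighbouring genes had a mean of 43.6% and a range of 32.5% to 54.5% (p = 0.662, same permutation test). The direction turned with the matching, so a moderate excess is not excluded. The pooled list would also not measure Hand binding if replicate 2 lacked the tag, so the explanation stays open. A mock precipitation or another tagged factor was not analysed here, so a factor-independent signal at open promoters stays open as a hypothesis.

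The higher shares of forkhead, Mef2 and GATA words may come from the A and T content of the summits. Words with the same letters in other orders had a summit-to-flank ratio at least as high in 61.5% of cases for forkhead, 68.5% for Mef2, 54.0% for GATA and 10% for DREF. The lower share of CANNTG was matched by 18.3% of its reordered words and that of CATCTG by 29.1%. For the ETS word 0% of 200 reordered words reached its ratio of 3.83, with both flanks averaged as background (0.257%) in this test, so composition is argued against there, on 34 peaks. No biological explanation was tested.

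Peaks strong in only 1 replicate showed no excess of Hand's organs or words that passed, in sets too small to exclude a moderate one. Of the 3310 strongest replicate 3 peaks, 352 had no summit within 250 bp among the 10000 strongest replicate 2 peaks. Counterparts ranked lower were not looked for. These 352 peaks had E-boxes at 42.0% of summits against 40.1% of flanks (p = 0.650, exact McNemar test). They lay at 9.09% of the 77 genes of the Hand-organ lists against a mean of 7.75% in random lists (p = 0.776, permutation test, two-sided). The 278 replicate 2 peaks chosen in the same way had E-boxes at 41.4% of both windows.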
